A study of Mus musculus with 8 samples.

How the data were processed

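RNA was profiled in colon tissue of BALB/cA mice, wild type or DCIR knockout, in 8 libraries of 1 per group. Total RNA came from flash-frozen colon and polyps and was made into libraries with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols. The groups were steady state, day 12 of DSS, non-polyp tissue at day 112 and polyp tissue at day 112, each in both genotypes, and every group was read from the sample title.

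The authors deposited 3 values per gene, per the file headers: coverage, which is the mean signal per base, FPKM, which divides by length and by library size, and TPM, which divides by length and scales to a fixed library total. The tool was StringTie and the build GRCm38, also called mm10, per the submitters' processing notes, and its version, the aligner and the annotation release are not given in the sources used here. The files list 54715 annotated genes, of which 54688 were in all 8 libraries, and 6 of the files also list loci assembled from the reads. Annotated TPM summed to between 895587 and 940132 per library, probably because the authors' scaling in the deposited TPM columns includes other loci. The DSS files list no such loci, so this cannot be seen there. No annotated mitochondrial genes were listed, so mitochondrial transcripts were not analysed here.

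Read counts were not given. The most common ratio of the deposited coverage to FPKM in a library implies its aligned bases, and ran from 2.70 gigabases in knockout DSS to 3.35 gigabases in wild-type DSS. Depth therefore differed by little between libraries, but no counting interval can be set on a single value, and a TPM of 0 is given as listed at 0. Whether the counting used strand is not given, so genes that overlap on opposite strands, and close paralogs such as Mcpt1 and Mcpt2 or Hspa1a and Hspa1b, may share reads.

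TPM and FPKM of a library should keep 1 fixed ratio, since both carry the same coverage. That ratio lay between 1.84 and 2.22, and 199371 annotated values above a low limit were checked with a tolerance of 0.1%. In 10 genes, 35 values departed from it, and these genes, with 13 genes that had several rows, were left out of tests, counts and lists. For the 10 genes the deposited TPM is printed beside a restored TPM that keeps the ratio. A restored value is the TPM of the assembled locus of the same library where the deposited one equals the other genotype's locus. Otherwise it is the deposited TPM after whole numbers were taken off TPM and FPKM, and coverage was not restored. This is a departure from using all values as deposited and was decided after the files were examined.

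Tests ran on log2(TPM + 1) for 16855 genes with a mean TPM of at least 1, so a fold change understates low genes. A linear model with stage and genotype was fitted to all 8 libraries with limma 3.58.1 and its intensity trend, which left 3 residual degrees of freedom. Its contrasts were knockout minus wild type, DSS minus steady state, non-polyp at day 112 minus steady state, and polyp minus non-polyp, each with Benjamini-Hochberg adjustment. With no differences at all, a share of 0.05 of the genes is expected at an unadjusted p under 0.05. Counts at that level are to be read against that share. The residual spread holds differences between animals together with any dependence of the genotype effect on stage, and nothing says which libraries share an animal. The submitters' design text counts 5 colon samples of 1 replicate each, whereas 8 are listed, so whether a library is 1 animal or a pool is not settled, nor is what the spread between libraries measures. Single pairs of libraries were compared with no test, as the log2 difference and the count of genes that differed at least 2-fold.

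Of 34 gene lists, 32 had at least 4 measured members, and the list of sex-linked genes was left out of the tests by choice. The other 31 were tested with camera and its preset correlation, which was repeated with an estimated correlation, and with fry in its directional and mixed forms. In single pairs, a list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, which describes those libraries and is no test. On simulated data with 200 changed genes of 16855, the genotype test recovered 0% of changes of 1 log2 unit, 73% of changes of 2 and 95% of changes of 4, with 0, 6 and 14 false calls. For the day 112 non-polyp test the shares were 0%, 32.5% and 88%. Each simulated genotype change was equal at every stage, whereas the real spread holds any dependence on stage. Where a real difference varies between stages, the shares may overstate what the genotype test recovers. Of 120 percentiles from simulated unchanged lists of independent genes, 5 fell outside the range of 2.5 to 97.5. Genes of the real lists vary together, so this does not show how often such lists would fall outside.

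Named genes follow a rule. Clec4a2 comes first. Each tested contrast names 8 genes per direction, all with the same sign in every pair. They are those with the largest fold change among genes that passed, or, where fewer passed, the largest by moderated statistic. Each single pair names the 5 largest per direction with a mean TPM of at least 5, and each described list up to 4 members with the largest difference, with Csf2, its receptor genes and the Stat5 genes beside the list on that pathway. Predicted gene models, pseudogenes and variable segments are not named, except where the text says so. Groups, tests, gene lists, this rule and 35 alternatives were fixed before the data were examined. Which lists to describe in a comparison was chosen later. The alternatives changed the pseudocount, the filter, the scaling, the unit and the trend, or left out single libraries or stages. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.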

Results

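RNA sequencing measured transcript levels in colon of BALB/cA mice that were wild type or lacked DCIR, an inhibitory C-type lectin receptor of dendritic cells and macrophages encoded by Clec4a2. The 8 libraries covered 4 stages in each genotype. These were steady state, day 12 of dextran sulfate sodium (DSS, which injures the colon epithelium), and day 112 of a protocol that adds the carcinogen azoxymethane, when polyps and non-polyp colon were sampled. Each group held 1 library. A difference between 2 libraries therefore has no replicate check, and p-values come only from a limma fit over all libraries. Aligned bases ran from 2.70 to 3.35 gigabases per library, and between 15986 and 16995 genes reached a TPM of at least 1. Log2 differences are on the scale of TPM plus 1.

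Clec4a2 (ENSMUSG00000030148, chromosome 6, 123106428 to 123143999, GRCm38) stood at 2.96 TPM in wild type at steady state, 4.33 after DSS, 2.74 in non-polyp tissue and 3.68 in polyp. The knockout libraries were listed at 0 after DSS, in non-polyp tissue and in polyp, and at 0.659 TPM at steady state, which was 22.3% of the wild-type value. Chosen after the values were seen, the predicted gene model Gm13394 on chromosome 2 showed the same order. It lay at 393 TPM in steady-state wild type, 71.3 in the library labelled steady-state knockout, and at most 0.545 in the other knockout libraries. Gm18840 and Gm44958 on chromosome 6, chosen likewise, stood at 13.1% and 15.5% of wild type in that library. Whether it is a mixture or comes from a heterozygous animal was not tested, so its label is in doubt. Among neighbouring lectin genes, Clec4a1 was present in both genotypes between 3.48 and 9.81 TPM, and so was Clec4n, which encodes Dectin-2, between 13.3 and 50.2 TPM. At low levels, Clec4b1 was lower in knockout at each stage, at 0.414 against 1.88 TPM at steady state, 0.430 against 0.447 after DSS, 0.337 against 1.14 in non-polyp tissue and 0.137 against 0.257 in polyp. Clec4a4 was at 0.0747 against 1.49 TPM in non-polyp tissue, and Clec4b2 was listed at 0 in knockout non-polyp and polyp and in wild-type DSS and polyp. The labels do not say which exons the knockout removes.

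**Figure D1:**
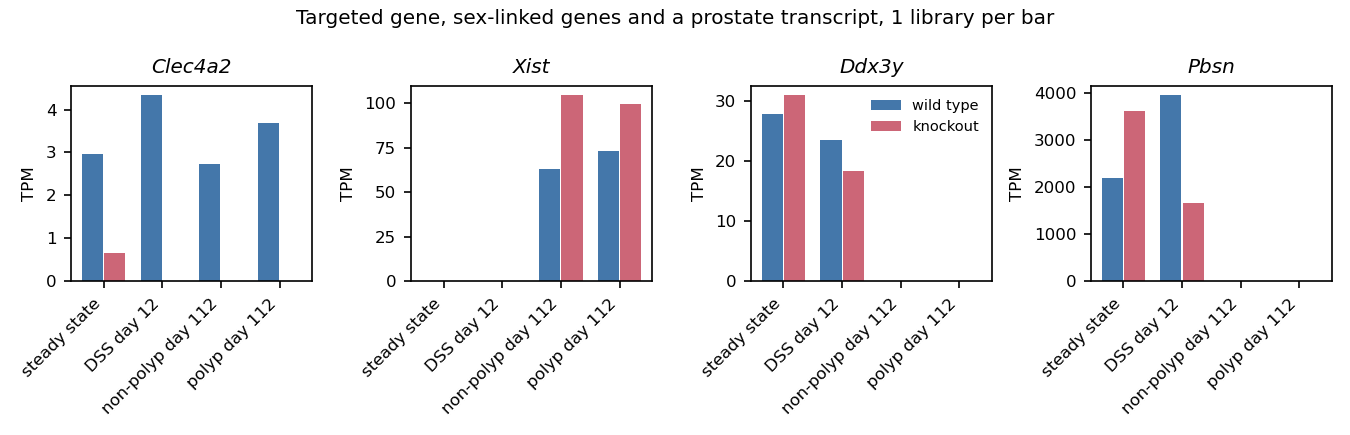
Bars show the TPM of Clec4a2, the sex-linked genes Xist and Ddx3y and the prostate gene Pbsn in wild-type (blue) and knockout (red) libraries, 1 library per bar, at the 4 stages on the horizontal axis. Clec4a2 was listed at 0 in 3 of the 4 knockout libraries, and Xist and Ddx3y divide the day 112 libraries from the others.

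Sex-linked genes divided the stages. All 4 day 112 libraries carried Xist, the X-inactivation transcript of females, at 63.0 to 104 TPM and were listed at 0 for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The 4 steady-state and DSS libraries held Ddx3y at 18.4 to 30.9 TPM, Eif2s3y at 24.1 to 58.4 TPM and Xist at no more than 0.114 TPM. They also held the prostate secretory gene Pbsn at 1652 to 3943 TPM and the prostate transglutaminase gene Tgm4 at 718 to 1611 TPM, against 0 and 1.35 to 14.1 TPM at day 112. Seminal vesicle genes stood apart in knockout DSS, where Svs5 was at 662 TPM and Svs4 at 541 TPM, against 0.540 and 1.08 TPM in wild-type DSS. Comparisons of day 112 with steady state therefore join libraries that differ in sex-linked genes, and comparisons of genotype at a stage do not. At steady state and after DSS, however, the genotypes carried unequal prostate and seminal vesicle transcripts. Pbsn stood at 2197 and 3606 TPM in wild type and knockout at steady state, and at 3943 and 1652 TPM after DSS.

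The series title names GM-CSF, a growth factor of myeloid cells encoded by Csf2, and STAT5, which signals from its receptor. The deposited TPM of Csf2 was 7.87 in wild-type and 70.1 in knockout DSS, 10.3 and 28.4 in non-polyp tissue, and 50.0 and 141 in polyp, and it was listed at 0 in both steady-state libraries. Those 6 values did not keep the ratio of TPM to FPKM of their library, and the restored TPM was 0.873 and 0.141 after DSS, 0.250 and 1.43 in non-polyp tissue, and 1.96 and 1.11 in polyp. An assembled locus that overlaps Csf2 at other coordinates gave 2.24 TPM in knockout polyp, so the order of the genotypes in polyp is not settled. Stat5a was deposited at 54.9 TPM in knockout DSS and 128 TPM in knockout polyp and was restored to 4.90 and 8.45 TPM, and in wild-type polyp it went from 14.4 to 4.43 TPM, where an overlapping assembled locus gave 8.39 TPM. Stat5b went from 47.2 to 9.18 TPM in knockout DSS, from 262 to 12.5 TPM in knockout polyp and from 20.7 to 10.7 TPM in wild-type polyp. Values that kept the ratio were Stat5a at 6.21 and 17.5 TPM in the libraries labelled steady-state wild type and knockout, 9.29 TPM in wild-type DSS, and 3.56 and 4.22 TPM in non-polyp tissue. The assembled loci that overlap Stat5a gave 10.4 and 17.8 TPM at steady state and 8.98 and 8.22 TPM in non-polyp tissue, so the size of the Stat5a difference at steady state and its direction in non-polyp tissue depend on the locus read. Stat5b was at 15.9 and 18.7 TPM in the steady-state libraries, 13.3 TPM in wild-type DSS, and 11.8 and 12.9 TPM in non-polyp tissue.

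**Figure D2:**
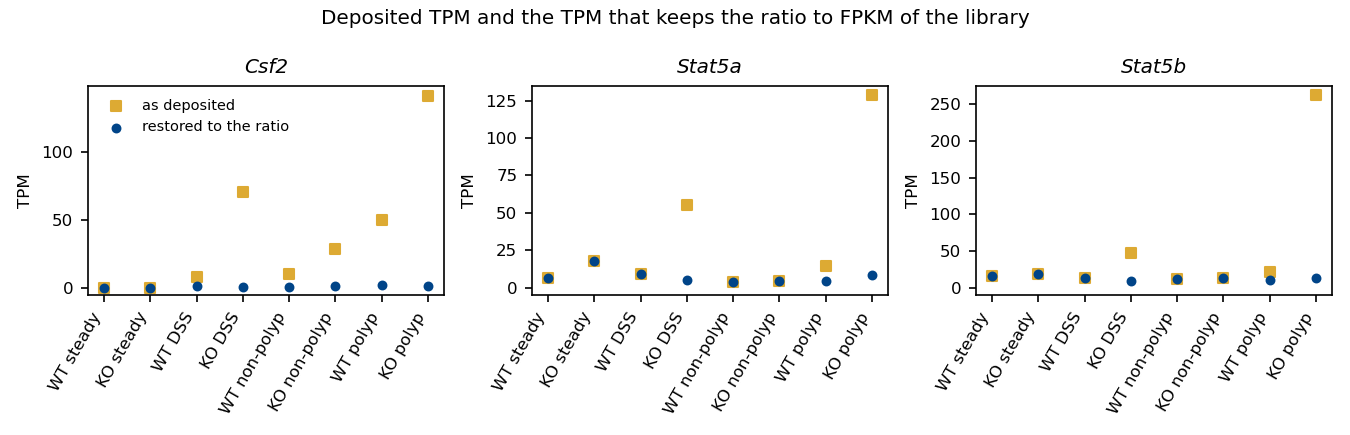
Squares show the deposited TPM and circles the TPM restored to the library's ratio of TPM to FPKM for Csf2, Stat5a and Stat5b in the 8 libraries on the horizontal axis. The deposited Csf2 value reaches 141 TPM in knockout polyp, and the restored values reach at most 1.96 TPM.

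The same departure was found for Tnf, Il17a, Il17f, Cxcl1, Cxcl2, Cxcl3 and Cxcl5, which encode inflammatory cytokines and neutrophil-attracting chemokines. In non-polyp tissue Cxcl1 was deposited at 170 TPM in wild type and 1.80 in knockout, and the assembled loci of the same libraries gave 1.80 and 170 TPM. Cxcl2 likewise went from 167 and 3.84 TPM to 3.84 and 167 TPM, Cxcl5 from 110 and 1.43 TPM to 1.43 and 110 TPM, and Tnf from 21.2 and 2.45 TPM to 2.45 and 21.2 TPM. In polyp, Cxcl1 went from 128 and 80.9 TPM to 80.9 and 128 TPM. Wild-type Il17a went from 10.4 to 0.448 TPM after DSS and from 32.7 to 2.74 TPM in polyp. How these values arose is not recorded in the sources used here, and none of the 10 genes enters the tests, counts or lists that follow.

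The first question was what loss of DCIR changes across all stages. Bcl2l14, an apoptosis regulator on chromosome 6 (134396318 to 134438736), had the strongest statistic, at 9.69 TPM in wild type and 104 in knockout after DSS, 7.37 and 40.6 in non-polyp tissue, and 5.67 and 39.4 in polyp, with 73.1 TPM in the library labelled steady-state knockout. Its log2 difference was 2.71 ± 0.20 (SE; limma adjusted p = 0.165), so it did not pass. Higher in knockout at every stage without passing were also the immunoglobulin constant gene Ighg2b (1.48), the splicing factor gene Bcas2 (1.37), Sbno1 (0.90), Klra17 (1.40), the chromatin gene Jarid2 (1.76), the thioredoxin gene Txn2 (1.36) and the lymphocyte activation marker Cd69 (1.30). Lower without passing were Clec4a2 itself (-1.95 ± 0.27, limma adjusted p = 0.705), the presenilin gene Psen2 (-1.36), the chemokine gene Cxcl12 (-0.79), Ppa2 (-0.59), Matn4 (-1.30), Chchd2 (-1.19), Depp1 (-1.06) and Enpp5 (-0.84). No gene passed with limma, and 736 were at an unadjusted p under 0.05, a count that was 254 without either polyp library and 1558 without either DSS library. Without either steady-state library, or without both, 1 gene passed, the predicted gene model Gm13394, named after its values were seen.

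Among the lists, all 25 measured WNT target and crypt stem cell genes were higher in knockout by the fitted effect, with a median log2 difference of 0.90 (camera adjusted p = 0.000349), led by the WNT antagonists Wif1 (1.88) and Notum (1.58) and by Lef1 (1.54). The pairs did not all share that direction, with WNT medians of 0.21 at steady state, -0.30 after DSS, 3.23 in non-polyp tissue and 0.29 in polyp. Wif1 was lower in knockout after DSS (2.09 against 4.06 TPM) and in polyp (503 against 626 TPM), as was Notum (0.0929 against 0.322 TPM and 249 against 317 TPM). With an estimated correlation the camera adjusted p was 0.911 for this list and for each list called below for genotype. Of 16 measured GM-CSF and STAT5 pathway genes 14 were higher, with a median of 0.39 (camera adjusted p = 0.0192). Its leading members were the GM-CSF receptor subunit gene Csf2rb (1.06 ± 0.36), Bcl2 (0.73), Osm (0.67) and Csf2rb2 (0.63). All 14 measured immediate early and stress genes were higher (median 0.65, camera adjusted p = 0.00278), with Fosb at 1.42 and Atf3 at 1.09, and 1 member passed adjusted over the list alone. All 13 smooth muscle genes were lower (median -1.10, camera adjusted p = 7.67e-07), including Des (-1.69), Cnn1 (-1.65) and Synm (-1.50). Absorptive colonocyte genes were lower in 18 of 25 (median -0.40, camera adjusted p = 1.99e-05), with Fabp2 (-2.05), Aqp8 (-1.75) and Sult1a1 (-1.60), and goblet cell genes in 11 of 13 (median -0.66, camera adjusted p = 8.65e-05), with Klk1 (-1.40) and Zg16 (-1.35).

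Camera called 10 lists for genotype with its preset correlation and 0 with an estimated one. Directional fry called none, and its mixed form, which ignores direction, called the Dcir and Dectin-2 cluster list (mixed fry adjusted p = 0.0129), which holds Clec4a2. No single member passed over all genes. Most of these differences lay in the non-polyp pair, where the median smooth muscle difference was -4.19, against 0.08 at steady state, 0.16 after DSS and -0.73 in polyp. Mean and median differed in sign for the Dcir and Dectin-2 cluster list (-0.02 and 0.24), the matrix and fibroblast list (-0.07 and 0.05) and the endothelial list (0.02 and -0.06). The median of all genes was 0.10 and moved to 0.00 under median-of-ratios rescaling.

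At steady state the library labelled knockout carried more fat-tissue transcripts than wild type. Adipoq, the adiponectin gene, was at 40.4 against 0.0979 TPM, Car3 at 310 against 7.82, Cfd at 222 against 9.46, Cyp2e1 at 94.1 against 2.31 and the lipogenic gene Thrsp at 36.1 against 1.75. Adipocyte markers had a median log2 difference of 3.74, above all random lists (percentile 100). All 21 interferon-stimulated genes were higher (median 0.99, percentile 100), with Ifit1 at 78.4 against 20.4 TPM, Ifit2 at 35.8 against 9.25, Usp18 at 24.6 against 7.73 and Ifit3 at 20.8 against 6.79. B and plasma cell markers (median 0.87, percentile 100) included Cr2 at 24.8 against 8.69 TPM, Ighm at 289 against 119 and Cd79a at 79.8 against 33.7.

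MHC class II genes were also higher in that library (median 0.77, percentile 99.99), with H2-Oa at 12.8 against 5.68 TPM, Ciita at 14.1 against 6.64 and H2-DMb2 at 32.4 against 17.3. Macrophage and monocyte markers were higher in 17 of 18 (median 0.57, percentile 100) and dendritic cell markers in 11 of 12 (median 0.61, percentile 99.94). The GM-CSF and STAT5 list had a lower median of 0.37 (percentile 99.2), with Ccl22 at 5.91 against 2.44 TPM, Csf2rb at 12.3 against 6.32, Irf4 (log2 difference 0.70) and Csf2ra at 19.3 against 15.5. Lower were the phosphate transporter gene Slc34a2 (1.67 against 21.2 TPM), Nupr1 (34.1 against 135), Hoxa3 (2.44 against 10.4), Zfp444 (6.22 against 22.7) and Lrmp (22.7 against 72.7). In all, 804 genes differed at least 2-fold, 605 of them higher, with no replicate check.

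After DSS the knockout library carried fewer neutrophil transcripts. The calprotectin genes S100a9 and S100a8, abundant in neutrophils, were at 2.10 and 0.859 TPM against 136 and 79.3 in wild type, Retnlg at 0.757 against 9.90 and the decoy receptor gene Il1r2 had a log2 difference of -2.48. Neutrophil markers had a median of -1.75 (percentile 0). All 13 matrix metalloproteinase genes were lower (median -0.82, percentile 0), with Mmp10 at 2.33 against 17.5 TPM, Mmp9 at 1.07 against 7.50, Mmp3 at 5.24 against 16.9 and Adamts4 at 0.533 against 3.22. Matrix and fibroblast genes (median -0.72, percentile 0) included Timp1 at 4.68 against 17.1 TPM, Wnt5a (log2 difference -1.24) and Col1a1 at 73.3 against 167. Macrophage and monocyte markers were lower in 16 of 18 (median -0.58, percentile 0), led by Arg1 at 0.271 against 14.4 TPM, with Cd14 at 65.3 against 106 and the efferocytosis receptor gene Mertk higher at 16.5 against 8.92.

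Absorptive colonocyte genes were higher in knockout DSS in 22 of 25 (median 0.51, percentile 100), such as the sodium channel gene Scnn1b at 31.0 against 14.7 TPM and Slc20a1 at 150 against 73.4, with Ces1g lower at 0.660 against 2.57. GM-CSF and STAT5 genes had a median of -0.22 (percentile 4.28), with Ccl17 at 3.01 against 6.09 TPM, Socs3 at 19.8 against 34.4, Osm at 0.640 against 1.66, Csf2rb at 6.37 against 5.60 and Csf2ra at 15.1 against 18.2. By size the list of single genes was led by the accessory gland genes Svs5, Svs4, Svs6 (232 against 0.101 TPM), Svs2 (221 against 0.0877) and Pate4 (71.3 against 0), all higher. Those lower were the accessory gland gene Msmb (0.174 against 327), S100a9, S100a8, Defb50 (37.3 against 980) and the acute-phase gene Saa3 (4.14 against 118). Defb50 kept the order of Msmb over the steady-state and DSS libraries. At steady state Defb50 stood at 125 TPM in wild type and 328 TPM in knockout, and in non-polyp tissue it was listed at 0. Whether its difference after DSS follows gland tissue was not tested. In total 785 genes differed at least 2-fold, 313 higher and 472 lower, with no replicate check.

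**Figure D3:**
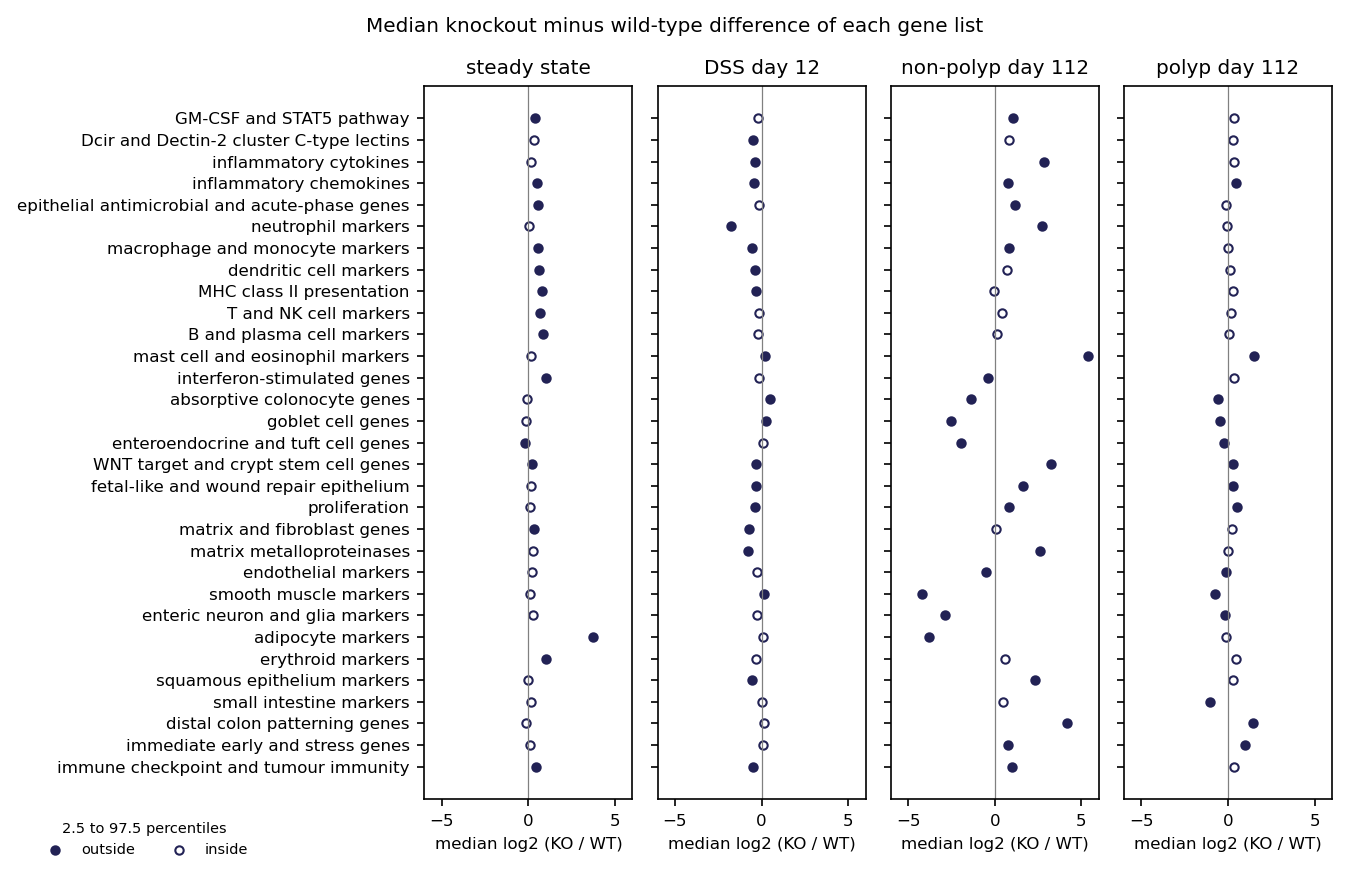
Each point is the median log2 difference, knockout minus wild type, of 1 gene list (vertical axis) in the pair of libraries of 1 stage (panel); filled points lie outside the central range of random lists given in the key. The neutrophil median was -1.75 after DSS and 2.73 in non-polyp tissue, and the adipocyte median was 3.74 at steady state and -3.78 in non-polyp tissue.

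In non-polyp tissue at day 112 the genotypes stood furthest apart, with 4150 genes differing at least 2-fold. All 25 WNT target and crypt stem cell genes were higher in the library labelled knockout (median 3.23, percentile 100), with Wif1 at 566 against 2.79 TPM, Notum at 331 against 2.41, Mmp7 at 400 against 8.77 and Apcdd1 at 186 against 3.89. Mast cell and eosinophil markers had a median of 5.35 (percentile 100), led by the mucosal mast cell proteases Mcpt1 (2191 against 11.5 TPM) and Mcpt2 (1133 against 5.54) and by Cma1 (94.2 against 0.367). Cytokines were higher (median 2.84, percentile 100), with Il11 at 78.0 against 0.872 TPM, Il6 at 22.2 against 0.124 and Il1b at 170 against 9.29. So were neutrophil markers (median 2.73, percentile 100), with S100a9 at 421 against 28.0 TPM, S100a8 at 208 against 15.6 and Mmp9 at 34.7 against 1.94.

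GM-CSF and STAT5 genes had a median of 1.05 in that pair (percentile 99.99), with Osm at 9.18 against 0.592 TPM, Csf2rb at 18.3 against 2.82, Csf2rb2 at 10.9 against 2.25, Socs3 at 107 against 29.5 and Csf2ra at 28.0 against 14.7. All 13 smooth muscle genes were lower (median -4.19, percentile 0), with Cnn1 at 31.7 against 1193 TPM, Des at 39.4 against 1333 and Mylk at 4.21 against 158. Of 6 distal patterning genes 5 were higher (median 4.15, percentile 100), with Hoxd13 at 130 against 1.91 TPM, Hoxd11 (log2 difference 4.88) and Hoxd12 at 29.5 against 0.197, while Hoxa13 was lower at 13.8 against 43.0. The wild-type library also held traces of pancreatic genes, with Ctrb1 at 21.9 TPM and Cela2a at 7.50 TPM, against 0 and 0.119 TPM in the library labelled knockout.

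Single genes higher in the library labelled knockout non-polyp were the metallothionein gene Mt4 (1632 against 4.85 TPM), the zinc transporter gene Slc30a2 (363 against 0.841), Mcpt1, Mcpt2 and the lipase-related gene Pnliprp1 (872 against 4.19). Lower were Mptx1 (2.30 against 281 TPM), Cfd (1.33 against 173), the fatty acid binding protein gene Fabp2 (13.2 against 747), Ctxn3 (0.364 against 70.0) and Reg3b (4.84 against 260). As deposited the genes at least 2-fold apart split into 2475 higher and 1675 lower, and under median-of-ratios rescaling into 1753 and 2184, a shift of the median gene by -0.21. The pair has no replicate check.

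In polyps, mast cell and eosinophil markers were higher in knockout (median 1.49, percentile 100), with Mcpt1 at 1776 against 311 TPM, Mcpt4 at 60.9 against 10.8 and Mcpt2 at 929 against 181. Proliferation genes were higher in 21 of 22 (median 0.53, percentile 100), with Mcm3 (log2 difference 1.06), Mki67 at 35.5 against 18.8 TPM and Kif11 at 20.7 against 11.8. All 14 immediate early and stress genes were higher (median 0.95, percentile 100), with the heat shock genes Hspa1a at 51.9 against 4.57 TPM and Hspa1b at 117 against 13.9, and Fosb at 55.7 against 7.63. Absorptive colonocyte genes were lower in 20 of 25 (median -0.60, percentile 0), with the water channel gene Aqp8 at 5.07 against 57.5 TPM, the carbonic anhydrase gene Car4 at 7.89 against 33.1 and Fabp2 at 3.45 against 14.2. Smooth muscle genes were lower in 12 of 13 (median -0.73, percentile 0), with Des at 17.2 against 69.5 TPM and Cnn1 at 17.3 against 60.1. Of the distal patterning genes 4 of 6 were higher (median 1.46, percentile 100), with Hoxd12 at 20.9 against 0.0749 TPM and Hoxd11 at 39.6 against 8.71, while Hoxa13 was lower at 10.8 against 16.6 and Hoxb13 at 216 against 239.

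The GM-CSF and STAT5 list had a median of 0.35 in polyps (percentile 93.6), with Csf2rb at 19.0 against 9.79 TPM, Irf4 at 2.65 against 1.12, Pim2 at 13.0 against 7.39 and Csf2ra at 28.8 against 22.1. Afdn was also higher, at 83.6 against 9.43 TPM. Lower single genes were Glycam1 (0.156 against 10.6 TPM), Aqp8, the retinal dehydrogenase gene Aldh1a1 (0.134 against 7.56), Pianp (1.12 against 14.1) and Rnaseh2b (1.31 against 15.4). Of 997 genes at least 2-fold apart, 619 were higher, against 426 of 930 under median-of-ratios rescaling, which moved the median gene by -0.15, and 248 of 558 in FPKM. No replicate check exists for this pair.

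The next question was what DSS changes, averaged over genotypes. The lowest limma adjusted p of any gene for DSS was 0.6945, in a gene that the naming rule leaves out. Of the genes higher after DSS that the rule allows, Ido1 led by statistic (log2 difference 2.36 ± 0.33, limma adjusted p = 0.777). Ido1, an interferon-induced tryptophan-degrading enzyme, was at 18.6 and 44.0 TPM after DSS in wild type and knockout against 3.45 and 6.54 at steady state. Higher without passing were also Actr8 (1.46), Dhrs9 (2.87), the transcription factor gene Cebpd (1.38), Cwh43 (1.52), the ghrelin gene Ghrl (1.62), Mrpl20 (0.93) and Myl7 (2.77). Lower without passing were Dennd1a (-2.33), Slc38a10 (-1.10), the WNT ligand gene Wnt5b (-2.38, from 4.28 and 5.99 TPM to 0.202 and 0.131), Trim30d (-1.85), Pou2f1 (-2.28), Zhx3 (-2.07), Plk3 (-2.06) and Ppp1r16b (-1.76). No gene passed with limma, and 904 were at an unadjusted p under 0.05. That count was 511 without the library labelled steady-state knockout, 558 without wild-type polyp, 556 without knockout polyp, 1738 without wild-type non-polyp and 1739 without the library labelled knockout non-polyp. The median of all genes was -0.12 and moved to -0.01 under median-of-ratios rescaling.

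All 21 interferon-stimulated genes were lower after DSS by the fitted effect (median -0.87, camera adjusted p = 8.93e-07), with Isg15 (-1.73), Ifit1 (-1.71), the antiviral gene Rsad2 (-1.70) and Oasl2 (-1.55). Their median was -0.06 in the wild-type pair and -1.49 in the knockout pair, whose steady-state library stood high in these genes. With an estimated correlation the camera adjusted p was 0.931 for this and each list called below for DSS. All 12 neutrophil markers were higher on average over genotypes (median 0.72, camera adjusted p = 0.00333), with S100a9 (3.30 ± 1.94), S100a8 (2.91), Il1r2 (1.18) and Stfa2l1 (0.90), but their median was 1.75 in the wild-type pair and -0.02 in the knockout pair. Antimicrobial and acute-phase genes were higher in 13 of 16 (median 0.77, camera adjusted p = 0.000154), with Saa3 (3.35), the phospholipase gene Pla2g2a (2.82), the nitric oxide synthase gene Nos2 (2.45) and Retnlb (1.42), and medians of 1.05 in wild type and 0.29 in knockout. Goblet cell genes were higher in 11 of 13 (median 0.35, camera adjusted p = 0.0116), with Clca4b (4.47) and Spdef (0.65) higher and Clca1 lower (-0.64). The GM-CSF and STAT5 list was not called (median -0.12, camera adjusted p = 0.783), with Csf2rb at 5.60 and 6.37 TPM after DSS against 6.32 and 12.3 at steady state. Camera called 7 lists with the preset correlation and 0 with an estimated one, and no member passed over all genes.

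By single pairs, wild-type DSS against steady state was led by Saa3 (118 against 0.251 TPM), the chloride channel accessory gene Clca4b (339 against 3.29), S100a9 (136 against 1.66), S100a8 (79.3 against 0.722) and the keratin gene Krt90 (48.2 against 0.128). Lower were the accessory gland genes Svs5, Svs4 (1.08 against 98.6 TPM), Svs2 and Pate4, and the DNA repair gene Xrcc4 (0.188 against 24.8). In knockout the accessory gland genes Sva (47.5 against 0 TPM), Svs1 (45.3 against 0.0790) and Svs6 (232 against 7.83) led, followed by Mcpt1 (43.7 against 2.77) and Mcpt2 (15.8 against 0.517). Lower in knockout were the accessory gland gene Msmb (0.174 against 92.0 TPM), Chn2 (0.833 against 25.6), the interferon-induced gene Ifi44 (0.982 against 21.4), Trak1 (18.3 against 193) and Ano6 (1.41 against 22.1). At least 2-fold apart were 1089 genes in wild type, 460 of them higher (338 of 664 in FPKM, at the same pseudocount and filter), and 1547 in knockout, 297 of them higher, which became 477 of 1337 under median-of-ratios rescaling with a shift of the median gene by 0.18. Neither pair has a replicate check.

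Between steady state and non-polyp tissue at day 112, averaged over genotypes, 55 genes passed with limma, 12 up and 43 down. Among those that rose were the gut lectin gene Itln1 (7.39 ± 0.57, adjusted p = 0.0115), the antimicrobial genes Ang4 (6.06, adjusted p = 0.0189) and Reg3g (5.40, adjusted p = 0.0113), and Sptssb (5.61, adjusted p = 0.0413). The haemoglobin gene Hba-a1 (2.52, adjusted p = 0.0438) and the immediate early genes Egr1 (1.69, adjusted p = 0.0413) and Jun (1.68, adjusted p = 0.0312) rose as well. Xist rose by 6.24 ± 0.29 (adjusted p = 0.00228), and the Y-linked genes Eif2s3y (-5.61, adjusted p = 0.00528) and Ddx3y (-4.92, adjusted p = 0.00326) fell. So did the prostate genes Pbsn (-11.46 ± 0.44, adjusted p = 0.00106) and Tgm4 (-8.27, adjusted p = 0.0094), with Tcaf3 (-8.09, adjusted p = 0.00211). Further genes that fell were the proton pump gene Atp12a (-5.10, adjusted p = 0.0209), the cytochrome gene Cyp2d12 (-4.97, adjusted p = 0.0204) and Slc37a2 (-5.47, adjusted p = 0.0438).

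The call count for day 112 moved with single libraries. It was 10 without steady-state wild type, 9 without the library labelled steady-state knockout, 36 without knockout DSS, 15 without either polyp library, 72 without the library labelled knockout non-polyp, of which 37 were among the 55, and 2238 without wild-type non-polyp. A fit without a steady-state or non-polyp library takes that stage's level in this contrast from a lone library. In every fit named here, the stage that lost a library adds nothing to the spread, which comes from the other stages only. Xist, Pbsn and Tcaf3 passed in each of these fits, and without any filter on low values 13 genes passed. At an unadjusted p under 0.05 there were 2786 genes, against 1708 without steady-state wild type, 1310 without the library labelled steady-state knockout and 5324 without wild-type non-polyp.

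Antimicrobial and acute-phase genes led the lists at day 112, with a median of 3.16 and 13 of 16 higher (camera adjusted p = 1.62e-05). With an estimated correlation the camera adjusted p was 0.803 for this list and for each list described below at day 112 as called. The medians were 1.74 in the wild-type pair and 2.29 in the knockout pair. Itln1, Ang4 and Reg3g rose, and Pla2g2a stood at 7.61 ± 1.27 without passing over all genes (limma adjusted p = 0.0905). Adjusted over the list alone, 7 rose and 2 fell. All 5 haemoglobin and erythroid genes were higher (median 2.52, camera adjusted p = 1.12e-07), with Hbb-bt at 3.15 and Hbb-bs at 2.58 beside Hba-a1, 1 call over all genes and 5 adjusted over the list alone. B and plasma cell markers were lower in 15 of 18 (median -1.50, camera adjusted p = 1.67e-05), where the low-affinity IgE receptor gene Fcer2a fell (-2.82, adjusted p = 0.0373) and Ms4a1 (-2.97) and Cr2 (-2.84) did not pass, with 11 lower adjusted over the list alone. Interferon-stimulated genes were lower in 19 of 21 (median -1.07, camera adjusted p = 3.09e-05), with Gbp5 (-1.75), Oasl2 (-1.69) and Gbp2 (-1.61), none passing over all genes and 4 adjusted over the list alone. Their median was -0.26 in the wild-type pair and -1.61 in the knockout pair, whose steady-state library stood high in these genes.

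All 22 proliferation genes were higher (median 0.56, camera adjusted p = 5.87e-07), with Birc5 (1.28), Cdk1 (1.03) and Rrm2 (0.98), none of which passed. Immediate early and stress genes were higher in 13 of 14 (median 1.08, camera adjusted p = 3.84e-07), with 2 calls over all genes and 5 adjusted over the list alone. All 6 distal patterning genes were lower (median -1.77, camera adjusted p = 0.0212), with Hoxd13 (-3.18 ± 1.33), Hoxd11 (-2.26) and Hoxd10 (-1.87), and their difference lay in wild type, where the median was -3.75 against -0.18 in knockout. The GM-CSF and STAT5 list was not called (median 0.04, camera adjusted p = 0.508), with Csf2rb at 2.82 and 18.3 TPM in non-polyp wild type and knockout. Camera called 15 lists with the preset correlation and 0 with an estimated one, where the absorptive colonocyte list, not described here, had an adjusted p of 0.875. Directional fry called none, and mixed fry called the antimicrobial (adjusted p = 0.00761), immediate early (0.00761), small intestine (0.0283), erythroid (0.0333) and B and plasma cell (0.0333) lists. Every comparison in this contrast carries the difference in sex-linked genes.

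In wild type the non-polyp library against steady state was led by Retnlb (772 against 1.87 TPM), an epithelial resistin-like gene, with Ang4 (185 against 0.306), Itln1 (118 against 0.0907), Reg3b (260 against 1.52) and Sptssb (121 against 0.221). In the knockout pair the leading genes were Pla2g2a (18377 against 21.5 TPM), Mt4 (1632 against 1.11), Mcpt2 (1133 against 0.517), Mcpt1 (2191 against 2.77) and Pnliprp1 (872 against 1.29). The genes lowest at day 112 were Pbsn, Tgm4, Tcaf3, Svs5 and the defensin gene Defb50 in both genotypes, with Defb50 listed at 0 against 125 TPM in wild type and 328 in knockout. In wild type 2089 genes were at least 2-fold apart, 660 of them higher, against 882 of 2011 under median-of-ratios rescaling with a shift of the median gene by 0.14 and 569 of 1369 in FPKM. In knockout there were 4236, of which 1607 were higher.

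The last question was how polyps differ from non-polyp tissue at day 112, averaged over genotypes. The lowest limma adjusted p of any gene for polyp was 0.138, in a gene that the naming rule leaves out. Of the genes higher in polyps that the rule allows, Lipo3, a lipase gene, led by statistic (2.16 ± 0.29, limma adjusted p = 0.858). It was at 5.62 and 9.77 TPM in wild-type and knockout polyps against 0.765 and 1.02 in non-polyp tissue. After it came Dnajc6 (2.15), Zbed5 (1.54), Ispd (1.76), Hpf1 (1.02), the biliverdin reductase gene Blvrb (1.34), Gdpd5 (1.49) and Agmat (2.22). Lower were Lpp, an adhesion gene, at 1.85 and 2.67 TPM in polyps against 13.1 and 21.0 (-2.45 ± 0.30), the drug efflux transporter gene Abcg2 (-3.65), Ttc8 (-1.81), the autophagy gene Atg7 (-1.80), Mier3 (-1.50), Sned1 (-1.48), Maml2 (-1.52) and Cib3 (-1.40), each at an adjusted p of 0.858. No gene passed with limma, and 496 were at an unadjusted p under 0.05, or 149 without wild-type polyp and 327 without knockout polyp. Without the library labelled knockout non-polyp 1529 genes passed, 733 up and 796 down, and 4608 were at an unadjusted p under 0.05, but in that fit a single wild-type library gives the non-polyp level and the spread comes from the other stages only.

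All 25 WNT target and crypt stem cell genes were higher in polyps (median 1.39, camera adjusted p = 1.19e-07), with Wif1 (3.60 ± 1.86), the matrilysin gene Mmp7 (3.08), Notum (3.07) and Sp5 (2.63). With an estimated correlation the camera adjusted p was 0.616 for this and each list called below for polyp. Matrix metalloproteinase genes were higher in 12 of 13 (median 0.83, camera adjusted p = 0.00288), with Mmp10 (2.96) and Mmp13 (2.54), and mast cell and eosinophil markers in 10 of 11 (median 1.72, camera adjusted p = 0.0113), with Alox15 (3.13) and Mcpt2 (2.26). All 13 smooth muscle genes were lower (median -2.31, camera adjusted p = 7.23e-09), with Des (-2.69), Synpo2 (-2.64), Cnn1 (-2.56) and Synm (-2.47). Absorptive colonocyte genes were lower in 21 of 25 (median -0.56, camera adjusted p = 1.27e-05), with Fabp2 (-3.65), Cyp2c55 (-3.48) and the chloride exchanger gene Slc26a3 (-2.26). The GM-CSF and STAT5 list was not called (median 0.32, camera adjusted p = 0.132), with Csf2rb at 9.79 and 19.0 TPM in wild-type and knockout polyps. Camera called 20 lists with the preset correlation and 0 with an estimated one, and no member passed over all genes.

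These list differences came mainly from wild type. There the polyp carried Mt4 at 2091 against 4.85 TPM, Pnliprp1 at 993 against 4.19, Slc30a2 at 312 against 0.841, Wif1 at 626 against 2.79 and the retinol transporter gene Stra6 at 134 against 0.0902. Lower in the wild-type polyp were Cfd (0.103 against 173 TPM), Car3 (log2 difference -6.37), Mptx1 (3.58 against 281), Pcp4 (0.0277 against 50.9) and Fabp2 (14.2 against 747). In knockout the largest differences were in Shld1 (23.3 against 0.565 TPM), Raly (360 against 43.7), Cdkal1 (10.4 against 0.701), Lipo3 (9.77 against 1.02) and Atp2c1 (47.8 against 9.86), and, lower, in Rnaseh2b (1.31 against 17.7), Abcg2 (0.827 against 10.6), Chmp4b (95.4 against 584), Lpp (2.67 against 21.0) and Sarnp (6.81 against 45.3). Genes at least 2-fold apart numbered 3191 in wild type, 1540 of them higher, and 484 in knockout, 221 of them higher. The median WNT difference was 2.89 in wild type and -0.06 in knockout, with no replicate check and no test of that contrast between genotypes.

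**Figure D4:**
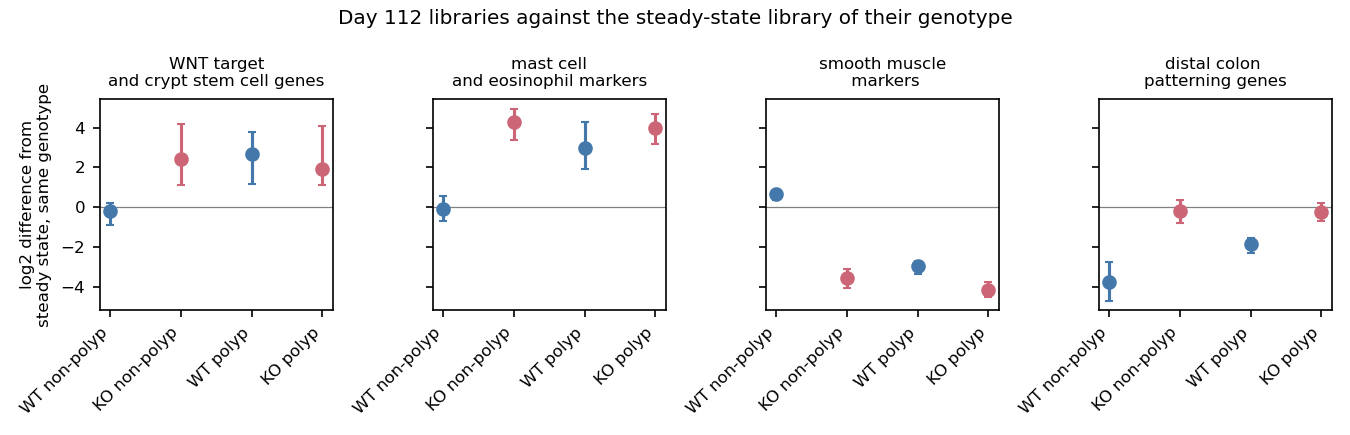
Points show the median log2 difference of a gene list in each day 112 library from the steady-state library of its genotype, and lines the quartiles over its genes, with wild type in blue and knockout in red. The WNT median was 2.41 in the library labelled knockout non-polyp, 2.67 and 1.92 in the wild-type and knockout polyps and -0.17 in wild-type non-polyp tissue.

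The knockout minus wild-type differences were then compared between stages across 16855 genes, which are not independent replicates. Pearson's r was -0.128 between steady state and DSS, 0.0423 between steady state and non-polyp tissue, 0.0786 between steady state and polyp, -0.142 between DSS and non-polyp tissue and -0.00517 between DSS and polyp. Between non-polyp tissue and polyp it was 0.390, with 68.0% of genes of the same sign. No library is shared by any of these pairs. Across genes the DSS difference of wild type and knockout had r = 0.183, the non-polyp difference 0.310 and the polyp difference 0.103.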

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

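All 3 tests of explanations in this part were chosen only after the result was seen. The results listed are those where the knockout minus wild-type difference stood high in 1 stage and low in another, and none of these contrasts between stages was tested. Of 205 named genes 42 differed in this way, of 32 lists 18, and of all 16855 genes 505.

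In non-polyp tissue at day 112 the library labelled knockout lay near the polyps. Its change from steady state correlated across genes, which are not independent, at 0.819 with the wild-type polyp and at 0.310 with wild-type non-polyp tissue. Polyp tissue in the sampled piece could give this, as the WNT median against steady state was 2.41 in that library, 2.67 in wild-type polyp and -0.17 in wild-type non-polyp. An exchange of labels between the day 112 knockout libraries does not account for it, since the other library also stood at 1.92. Position along the colon stays open, as the smooth muscle median was -3.56 but 3 distal patterning genes were higher and 3 lower (median -0.18), and so does a difference caused by the genotype itself, which was not tested.

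The gap in the knockout minus wild-type log2 difference between non-polyp tissue, where it was highest, and DSS, where it was lowest, was 9.09 for S100a8, 9.32 for S100a9, 8.80 for Saa3, 8.97 for Arg1, 9.17 for Stra6, 8.66 for Slc30a2, 5.41 for Retnlg, 4.71 for Il1r2, 4.34 for Stfa2l1 and 4.04 for Nos2. Between the same stages it was 7.79 for Mmp10, 6.49 for Mmp7, 5.64 for Mmp9, 2.60 for Mmp3, 2.98 for Adamts4, 4.24 for Timp1, 6.45 for Apcdd1, 2.53 for Wnt5a, 6.47 for Il11, 6.47 for Il1b, 6.94 for Krt90 and 6.20 for Clca4b. Mmp7 kept the order of the prostate gene Pbsn over the steady-state and DSS libraries. It stood at 142 and 239 TPM in wild type and knockout at steady state, and at 274 and 124 TPM after DSS. Whether its difference after DSS follows gland tissue was not tested. From steady state as the highest to non-polyp tissue as the lowest, the gap was 10.64 for Cfd, 9.94 for Car3, 9.65 for Adipoq, 9.60 for Cyp2e1, 6.81 for Mylk, 6.58 for Aldh1a1, 5.05 for Thrsp and 2.54 for Isg15. From steady state to DSS it was 9.74 for the accessory gland gene Msmb, 6.07 for Defb50, which kept the order of Msmb over those libraries, and 3.52 for Ifi44. From steady state to polyp it was 5.35 for Glycam1. From polyp to DSS it was 4.65 for Ano6 and 2.61 for Gbp5, and from DSS to non-polyp tissue 6.84 for Reg3b and 4.61 for Clca1. From DSS to steady state it was 4.98 for Xrcc4, 3.48 for Sarnp and 2.69 for Slc37a2, and from non-polyp tissue to steady state 3.89 for Lrmp.

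For lists, the gap in the median was taken between the stages of the highest and lowest percentile among random lists. These need not be the stages of the highest and lowest median, so a larger gap can lie between other stages. From non-polyp tissue to DSS the gap was 4.47 for neutrophil markers, 3.53 for WNT target and crypt stem cell genes, 3.44 for matrix metalloproteinases, 3.25 for inflammatory cytokines, 2.88 for squamous epithelium markers, 1.92 for fetal-like and wound repair epithelium and 1.49 for immune checkpoint and tumour immunity genes. From steady state to DSS it was 1.16 for macrophage and monocyte markers, 1.10 for MHC class II genes, 1.06 for matrix and fibroblast genes, 1.00 for dendritic cell markers and 0.90 for inflammatory chemokines. From steady state to non-polyp tissue it was 7.52 for adipocyte markers and 1.36 for interferon-stimulated genes. From DSS to non-polyp tissue it was 4.35 for smooth muscle markers, 2.81 for goblet cell genes and 1.91 for absorptive colonocyte genes, and from polyp to DSS 0.93 for proliferation genes.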

How the results depend on the processing

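The alternatives that kept the 10 genes with a departing ratio, or rescaled to the annotated total, were chosen only after the files were seen. For genotype, leaving out a library gave 0 or 1 calls, and 1 without both steady-state libraries. The DSS effect stayed at 0, and the polyp effect ran from 0 to 1529 calls, the latter without the library labelled knockout non-polyp. For non-polyp tissue at day 112 calls ran from 9 without the library labelled steady-state knockout to 2238 without wild-type non-polyp, and without a filter on low values 13 genes passed. With the estimated correlation, camera called 0 lists for genotype, 0 for DSS, 0 for polyp and 0 for day 112 non-polyp tissue.

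Counts of genes at least 2-fold apart moved with the pseudocount and the filter, and were lower in FPKM. With a pseudocount of 0.1, knockout against wild type gave 1428 at steady state, 1487 after DSS and 1800 in polyp. DSS against steady state gave 1838 in wild type and 2451 in knockout, and polyp against non-polyp 1053 in knockout. With a mean TPM of at least 5, the genotype counts were 426 at steady state, 444 after DSS and 594 in polyp. The DSS counts were then 635 in wild type and 892 in knockout, the non-polyp counts against steady state 1350 and 2684, and the polyp counts against non-polyp 2030 and 234. In FPKM the genotype counts were 393, 461 and 558, the DSS counts 664 and 809, the wild-type non-polyp count 1369 and the knockout polyp count 228. These FPKM counts cannot be put down to the unit alone, since FPKM values are about 2 times smaller, so that the same pseudocount weighs more and the filter kept 14926 genes.

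Across genes with a mean TPM of at least 5, which are not independent, r between the genotype differences was -0.127 for steady state and DSS, 0.0724 for steady state and non-polyp tissue, 0.0901 for steady state and polyp, -0.178 for DSS and non-polyp tissue, -0.0175 for DSS and polyp and 0.434 for non-polyp tissue and polyp. Between genotypes it was 0.204 for the DSS difference, 0.357 for the non-polyp difference and 0.112 for the polyp difference. Most list medians of single pairs shifted somewhat. With a mean TPM of at least 5, 85 of 310 medians shifted by over 0.1 log2, and 172 of 185 that lay outside the percentiles of random lists still did. Of those 185, 2 turned sign, the chemokine median in polyps (0.45, then -0.03) and the checkpoint median of knockout non-polyp tissue against steady state (0.43, then -0.01). Under median-of-ratios rescaling 129 of 320 shifted by over 0.1 and 189 of 190 stayed outside. That rescaling moves the random lists nearly alike, so the latter count says little on stability. No paired analysis was possible because the labels give no shared replicate or animal numbers.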

Other observations

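The tests in this part were all chosen only after the result was seen. For Csf2, Stat5a, Stat5b and 7 cytokine and chemokine genes, 35 deposited values departed from the ratio of TPM to FPKM of their library. Rounding of the deposited digits is excluded, since the smallest departure was 0.654% and the largest of all other values 0.0073%. For 16 of the 35 the value equals the assembled locus of the other genotype's library, so an exchange between the genotypes' rows fits those. For the other 19 an exchange does not hold, as 0 of them equal the other genotype's TPM, and all 19 regained the ratio once whole numbers were taken off. How either set arose is not recorded in the sources used here.

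Genes with the same sign of the genotype difference at every stage, among them Bcl2l14, Cd69, Klra17, Pianp and Cxcl12, gathered near Clec4a2. Of the 100 strongest, 13 lay within 20 Mb of it, against 1.71 by the share of genes there and 8 in the highest other window. Flanking sequence carried with the targeted allele could give this. The highest count over 7 other balanced divisions of the libraries was 4. Uneven gene density with chance is not excluded, since 7 divisions are too few to decide. The 8 genes of the highest other window, on chromosome 12, were Crip1 and immunoglobulin heavy-chain genes such as Ighg2b. Because such genes can vary together, that window says little on gene density. A gene family with shared reads does not by itself account for the gathering, as by symbol 1 of the 13 is a Klr or Clec gene. Relatives under other symbols were not counted. No sequence variants were examined, so the flanking explanation remains open.

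The count of genes called for genotype by limma was 0, so a comparison with other divisions of the libraries decides nothing, since each of the 32 that could be fitted must give at least that many. The highest of the others was 5. At an unadjusted p under 0.05 there were 736 genes, and 11 of these divisions gave more. Most of the 11 were not balanced over stages. Unbalanced divisions come in pairs that give the same fit, so the 11 are not separate fits. Each takes its difference only from the stages that it splits. Among the other balanced divisions the highest count was 1950 and the next 637.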
